A study of Rattus norvegicus with 20 samples.

How the data were processed

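Single cells of dissociated rat mammary gland were measured by droplet RNA sequencing with the 10x Genomics 5' HT v2 chemistry. Tissue was digested with collagenase IV and hyaluronidase before loading. The authors aligned and counted the reads with Cell Ranger 6.1.2, and the deposited values are raw UMI counts per gene and cell barcode, with no normalization, in 1 matrix per library for 25399 genes. The files were checked to hold non-negative whole numbers, and 148 gene symbols were shared by more than 1 identifier. The labels name neither strain, sex, cycle stage, sequencing batch nor the fate of lymph nodes.

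Groups and replicate numbers were taken from the labels. They gave 4 libraries each at 3, 6, 12 and 22 months and, at 2 months, 2 libraries each of vehicle and recombinant midkine, 20 libraries in 6 groups. No library was left out. The depth per library is in the results text. Shares of counts carry the precision of their cell numbers, and each interval or limit from a count of 0 (3 counts of the total, Wilson intervals at 95% otherwise) covers counting error only. The comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Alternatives chosen after seeing the data were a free-RNA rule, which kept only genes at 1/5 or more of their level in the class where they were highest, and the addition of an unnamed cluster to the fibroblasts.

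Barcodes were kept with at least 300 genes, at least 500 UMIs and at most 15% mitochondrial UMIs. Doublets were scored per library with Scrublet in scanpy 1.11.5 (scikit-learn 1.9.0, scikit-image 0.26.0), and the highest-scoring cells were removed at 0.4% of cells per 1000 cells. Clustering of all kept cells used scanpy and leidenalg 0.10.2 with 2000 variable genes, 40 principal components, 20 neighbours, resolution 1.0 and seed 1, and no batch correction. Epithelial clusters were clustered again. Each of 62 clusters was named by hand from marker lists fixed beforehand, where at least 3 markers of the class were detected in at least 10% of its cells and markers of no other class were more frequent among its 10 leading genes. The others stayed unnamed, most with markers of several classes, cycling genes or few UMIs. Cell counts, library depths and shares were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

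UMIs were summed per library and class where a library had at least 20 cells of it. Differential expression used edgeR 4.0.16 in R 4.3.3, with data.table version 1.17.8, using TMM factors, filterByExpr by group, 1 model of all 6 groups and the quasi-likelihood F test. P-values were adjusted by Benjamini and Hochberg within each class and comparison at a threshold of 0.05. The SE of a log2 change is its size divided by the square root of F. Every adjusted p of a gene in the text comes from edgeR unless another tool is named. In the midkine experiment, whose groups have 2 libraries, edgeR pools the spread of genes and of all 6 groups. Compared were 22 with 3 months and midkine with vehicle in hormone-sensing, secretory and basal cells, fibroblasts, endothelial cells, macrophages and T cells, and 12 and 6 with 3 months in the 3 epithelial classes.

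Named genes were, per class and comparison, the 6 with the largest log2 change in each direction (3 at 12 and 6 months) among genes past the threshold. They needed a mean log2 CPM of at least 4, an informative symbol outside the antigen receptor segments, no overlap between the libraries of the groups, and a mean level of at least 1/5 of the class where the gene was highest. Mdk is given for each class and comparison tested. From each list the 4 called members with the smallest p could be named. The 34 lists covered midkine and its receptors, cholesterol synthesis, fatty acid synthesis, ATF4 and mTORC1 targets, FOXO targets, senescence, interferon response, MHC class I and II, immediate early genes, heat shock, collagen and matrix, milk, oestrogen and progesterone response, luminal and basal identity, proliferation, complement, NF-kB chemokines, lipid-associated and resident macrophages, cytotoxic and naive T cells, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, and markers of erythrocytes, plasma cells, fibroblasts, macrophages, T cells, epithelium, endothelium and adipocytes. Some lists share members. Lists with at least 5 members tested went through camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over lists and classes of a comparison, and through camera with an estimated correlation and fry as alternatives. Genes called at 22 months were tested together under midkine with fry, signed by their direction with age and adjusted over 7 classes.

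Shares of cells were compared between 22 and 3 months as log2 of cells plus 0.5 over the total plus 1, by exact two-sided permutation of the 8 libraries, adjusted over 12 classes, and over 3 classes for shares of the epithelium. The smallest p is 0.0286 for 4 against 4 libraries and 0.333 for 2 against 2, so midkine shares have no test.

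The model was tested on simulated data with known changes at the same library and class sizes. Of its calls 1.9% to 8.03% were false at 22 months and up to 15.8% with midkine. Alternatives were DESeq2 1.42.0 with its own size factors and filter, RLE factors, no low-count filter, doublets kept, a stricter cell filter (500 genes, 10% mitochondrial UMIs), resolution 0.5 with classes named again, only the libraries of the experiment, the replicate number as a block, leaving out each library in turn, raw percentage points for shares, and the additions named above.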

Results

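The series addressed how cells of the rat mammary gland change with age, and whether midkine, a secreted heparin-binding growth factor encoded by Mdk, takes part in those changes. Dissociated glands were profiled by single-cell RNA sequencing at 3, 6, 12 and 22 months of age, with 4 libraries per age. A second experiment used 2-month-old rats that received vehicle or recombinant rat midkine, with 2 libraries per treatment. Midkine was injected into the peritoneal cavity at 300 ug/kg, 3 times a week for 4 weeks. The 20 libraries held 235753 cell barcodes and 1003002614 UMIs (unique molecular identifiers, counting captured transcripts). Single libraries held 7016 to 16685 barcodes and 31199477 to 79688261 UMIs. The mean total per library was 67220000 ± 14700000 UMIs at 3 months (SD, n = 4) and 43670000 ± 7610000 at 22 months (SD, n = 4). It was 40110000 ± 2560000 with vehicle and 47710000 ± 23400000 with midkine (SD, n = 2 each). Levels are mean TMM-scaled CPM (UMIs of a gene in a cell class, scaled to a common total) ± SD over libraries, with n = 4 at each age and n = 2 in each treated group, and log2 changes carry ± SE. The files give gene identifiers without coordinates, and the genome build is not given in the sources used here.

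After filtering and removal of 10970 predicted doublets, 207780 cells remained and 183883 of them were assigned to a class by markers. The classes comprised 3 epithelial ones, namely 5713 luminal hormone-sensing cells, 17911 luminal secretory cells and 8519 basal cells. Stroma and vessels contributed 27712 fibroblasts, 12326 endothelial cells, 740 lymphatic endothelial cells, 3022 pericytes, 548 Schwann cells and 172 adipocytes. The immune classes were 46167 T cells, 35775 B cells, 19244 macrophages, 2942 dendritic cells, 2372 NK cells and 720 plasma cells. No cluster of neutrophils or mast cells was found. Unnamed clusters held 13.64% of the cells at 3 months, 11.72% at 6 months, 6.54% at 12 months, 4.28% at 22 months, 25.17% with vehicle and 24.14% with midkine. A class was often built from different clusters in different groups. Of hormone-sensing cells, 69.3% fell in one cluster at 22 months whose leading genes included Klk1, Spink8, Hpgd and Ppp1r1a, whereas 82.4% fell in another cluster at 3 months. Basal cells of all 4 ages shared a cluster, while those of the midkine experiment formed others. UMIs per cell also moved with age within classes. They went from 13980 ± 1580 at 3 months to 6486 ± 1500 at 22 months in hormone-sensing cells and from 8158 ± 870 to 9237 ± 1330 in secretory cells (SD, n = 4 each).

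Among named cells, T cells stood higher and B cells, NK cells and hormone-sensing cells stood lower in every library of 22 months than in any of 3 months. T cells made up 42.6% ± 6.1 at 22 months and 19.2% ± 5.57 at 3 months (SD, n = 4 each), a 2.28-fold difference. B cells made up 4.95% ± 2.24 against 35.3% ± 7.15, 7.57-fold lower. Hormone-sensing cells, which carry the oestrogen and progesterone receptors, made up 0.83% ± 0.118 against 3.56% ± 0.584, 4.29-fold lower. NK cells made up 0.885% ± 0.211 against 1.63% ± 0.170. In these 4 classes the exact two-sided permutation test gave p = 0.0286, the smallest possible, and 0.0857 after adjustment over 12 classes, so none passed. Plasma cells stood at 0.364% ± 0.249 against 0.906% ± 0.483 (exact p = 0.0571, adjusted 0.137). The other 7 classes gave exact p between 0.114 and 0.886, including fibroblasts (19.3% ± 6.44 against 11% ± 7.15), macrophages (10.7% ± 1.93 against 9.38% ± 3.78) and endothelial cells (4.62% ± 0.538 against 3.75% ± 0.652). Within the epithelium, hormone-sensing cells stood at 6.97% ± 3.08 against 22.6% ± 3.19, without overlap (exact p = 0.0286, adjusted 0.0571). Basal cells stood at 26.3% ± 4.72 against 17.7% ± 2.61 of the epithelium (exact and adjusted p = 0.0571). With a stricter cell filter both passed, at adjusted p = 0.0429 each. These leave out an unnamed epithelial cluster (842 cells at 3 months, 21 at 22 months). At 6 and 12 months T cells made up 19.5% ± 4.31 and 26.3% ± 2.45, and B cells 21.6% ± 11.6 and 18.9% ± 3.77 (SD, n = 4 each), without a test. All shares are relative, so a rise in one class lowers the others. The labels do not say whether mammary lymph nodes were removed.

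**Figure D1:**
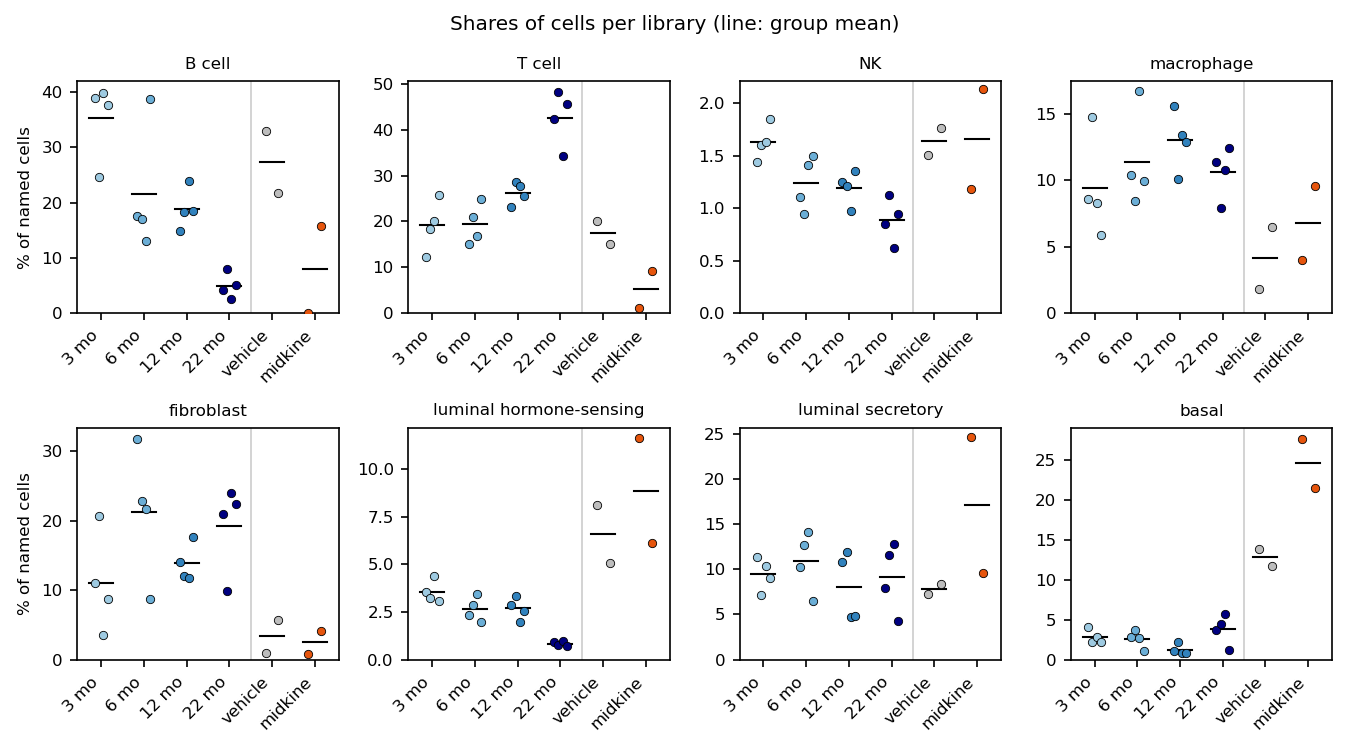
Percentage of named cells in each class, for 8 classes (y axis) in the 4 ages and the 2 treated groups (x axis), 1 point per library, with a line at each group mean. B cells lay at 35.3% at 3 months and 4.95% at 22 months, and T cells at 19.2% and 42.6%.

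The comparison of 22 with 3 months asked which genes change with age inside each class. Every class compared changed broadly. In luminal secretory cells, which make milk, 3163 genes rose and 3123 fell of 11661 tested. In T cells 2518 rose and 2446 fell of 11117. In hormone-sensing cells 1120 rose and 1025 fell of 10644, and in macrophages 1108 rose and 890 fell of 10795. Smaller counts came from fibroblasts (957 and 759 of 12671), basal cells (745 and 559 of 10584) and endothelial cells (743 and 595 of 9974). The counts do not rank the classes, because numbers of cells and depths differed. Without 1 library, the basal count of 1304 was 835 (replicate 2 of 22 months) and the fibroblast count of 1716 was 1085 (replicate 3 of 22 months). Of 34 gene lists fixed beforehand, 31 had at least 5 members tested in some class. Over classes, 88 of 204 list tests passed at 22 months in camera with its preset correlation, 17 of 81 at 12 months, 19 of 81 at 6 months and 65 of 204 with midkine. With an estimated correlation 0 passed in camera, at lowest adjusted p of 0.216, 0.524, 0.848 and 0.285. By fry, which tests a list without comparing it with other genes, 97 passed at 22 months, 4 at 12 months, 7 at 6 months and 25 with midkine.

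**Figure D2:**
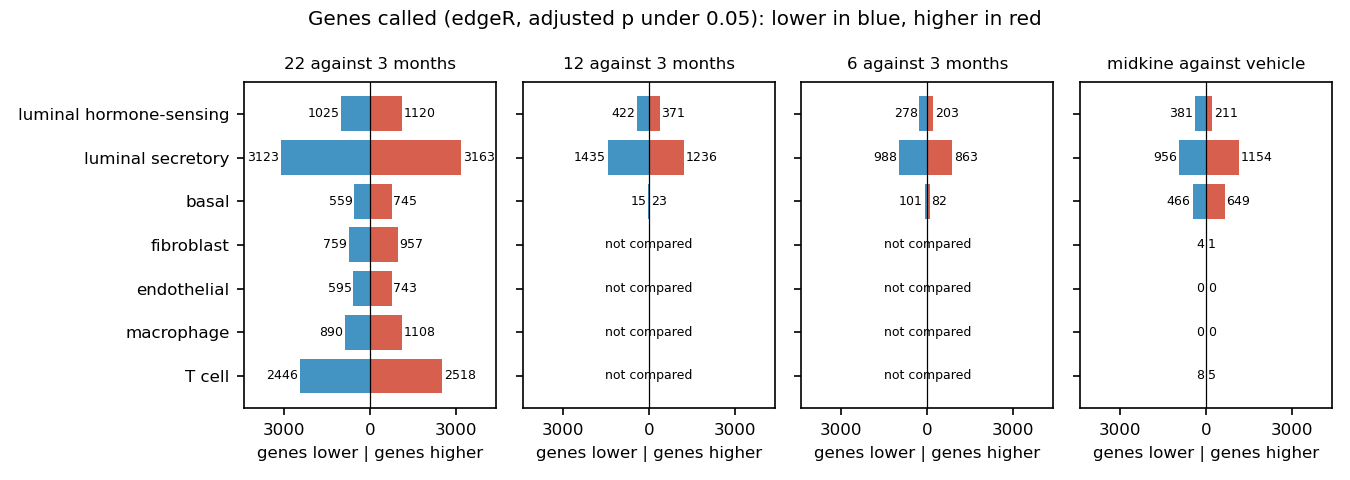
Number of genes lower (left) and higher (right) at adjusted p under 0.05 in each class and comparison, with comparisons that were not made marked as such. At 22 months the secretory bars reach 3123 and 3163 genes, and endothelial cells and macrophages show 0 with midkine.

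In luminal secretory cells at 22 months, transcripts of milk rose. The clusters of the class differed, as one led by Glycam1, Wap and Csn2 held 54.6% of its cells at 22 months and 0.2% at 3 months, and another held 2.2% and 61.7%. Csn2 (β-casein) rose from 2980 ± 4600 to 134000 ± 60000 CPM, a log2 change of 5.49 ± 1.15 (adjusted p = 0.000429). Wap (whey acidic protein) rose from 287 ± 451 to 23600 ± 21700 CPM, by 6.36 ± 1.06. Glycam1, a secreted mucin of milk, rose from 477 ± 678 to 124000 ± 76300 CPM, by 8.02 ± 1.03. Fabp3, a fatty acid binding protein of lactating cells, rose by 5.54 ± 0.61, and Wfdc3 by 6.21 ± 0.37. Ccn3 went from 0.0925 ± 0.131 to 268 ± 394 CPM. Of 19 milk and lactation genes tested, 12 rose and 2 fell (12 and 3 adjusted over the list alone), among them Lpo (4.51 ± 0.40), Pigr (3.23 ± 0.33) and Csn3 (2.24 ± 0.36). The list median was 0.74 (camera adjusted p = 0.00766, and adjusted p = 0.545 with an estimated correlation), and 0.41 without replicate 2 of 22 months. Lalba (α-lactalbumin) did not pass (-0.14 ± 0.29). The milk list was called higher in all 7 classes at 22 months, and in hormone-sensing cells Wap and Csn2 stood at 0.00439 and 0.00519 of the secretory level. In endothelial cells that call (0.56) ended without replicate 2, 3 or 4 of 3 months or replicate 2 of 22 months (0.36 to 0.63). Of 16 genes of fatty acid synthesis, 14 rose and 1 fell (14 and 1 adjusted over the list alone), with the transcription factor Srebf1 up by 3.56 ± 0.34 and the desaturase Scd2 by 3.64 (median 1.85, camera adjusted p = 2.56e-06, and adjusted p = 0.234 with an estimated correlation). Of 28 nuclear genes of oxidative phosphorylation 24 rose and 0 fell (24 and 0 adjusted over the list alone), among them Ndufs3 at 1.94 ± 0.21 (median 1.05, camera adjusted p = 6.47e-11, and adjusted p = 0.402 with an estimated correlation).

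Several stress and translation genes fell in the same secretory cells. Of 43 cytosolic ribosomal protein genes 0 rose and 41 fell (0 and 41 adjusted over the list alone; median -0.77, camera adjusted p = 1.32e-17, and adjusted p = 0.318 with an estimated correlation). Of 19 dissociation and immediate early genes, which tissue digestion can induce, 0 rose and 18 fell (0 and 18 adjusted over the list alone), including Fosb (-2.21 ± 0.26). Their median was -1.43 (camera adjusted p = 5.17e-07, and adjusted p = 0.396 with an estimated correlation). Of 17 FOXO targets 0 rose and 11 fell (0 and 11 adjusted over the list alone), with Pdk4 at -2.56 ± 0.23 (median -0.94, camera adjusted p = 0.000785, and adjusted p = 0.318 with an estimated correlation). Of 13 heat shock genes 1 rose and 10 fell (1 and 10 adjusted over the list alone), with Hspa8, a constitutive chaperone, at -1.88 ± 0.19 (median -0.79, camera adjusted p = 0.00998, and adjusted p = 0.527 with an estimated correlation). Of 17 genes of MHC class I presentation 12 rose and 2 fell (12 and 2 adjusted over the list alone), with RT1-A1 at 1.25 ± 0.11 (median 0.64, camera adjusted p = 0.00149, and adjusted p = 0.497 with an estimated correlation). The FOXO, heat shock and MHC class I calls were lost when genes under 1/5 of their level in the highest class were left out, at adjusted p = 0.0546, 0.0601 and 0.0603. Of 31 proliferation genes 24 rose and 2 fell (25 and 2 adjusted over the list alone), at low levels (Mki67 5.30 ± 0.76, Cdk1 5.46 ± 0.70; median 3.40, camera adjusted p = 0.000177, and adjusted p = 0.545 with an estimated correlation). Under the same rule that median was -0.07 (adjusted p = 0.754), and at the coarser clustering 0.99 (adjusted p = 0.252). A cluster of cycling luminal cells, with 62 cells at 3 months and 16 at 22 months, was unnamed and so left out. Of 16 luminal identity genes 3 rose and 7 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.143), among them the receptor Kit at -2.98 ± 0.27. Genes that fell furthest included Tmem154 (-5.82 ± 0.29), Dynlrb2 (-4.40 ± 0.36) and Fbln2, an extracellular matrix protein (175 ± 25 to 12 ± 7.64 CPM, -3.89 ± 0.28). All 12 named genes of this class kept their call without any 1 library.

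**Figure D3:**
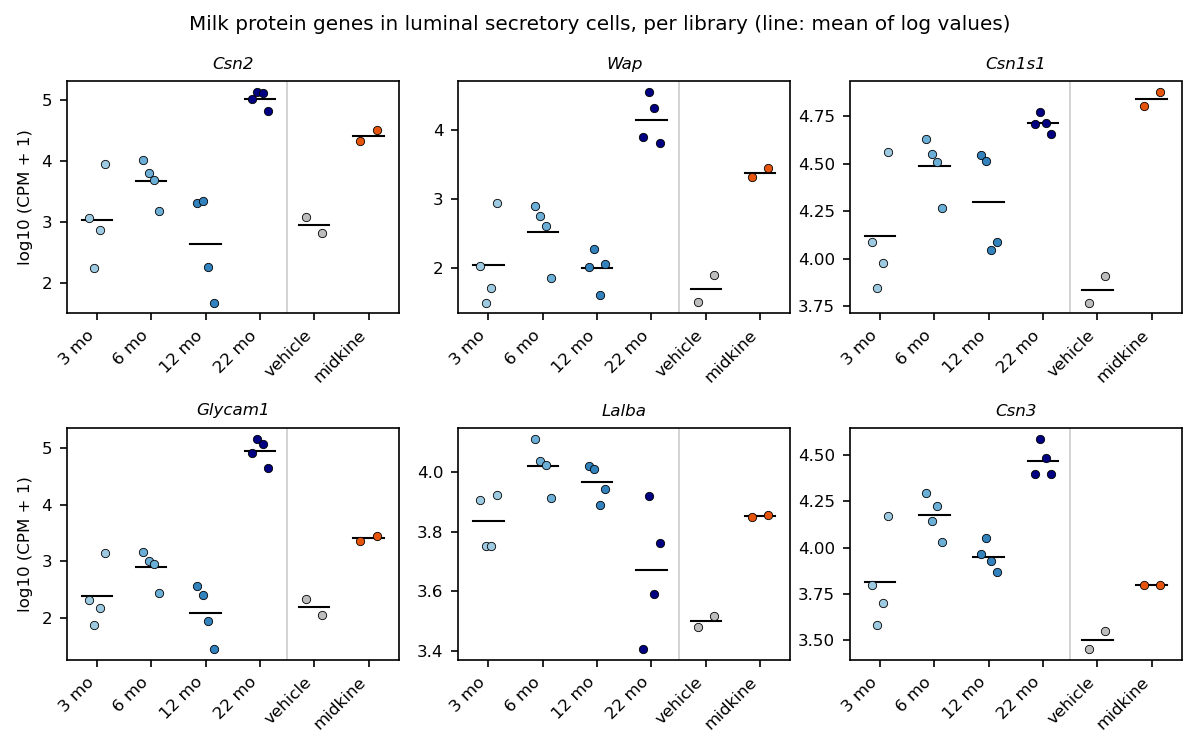
Csn2, Wap, Csn1s1, Glycam1, Lalba and Csn3 in luminal secretory cells, as log10 of plain CPM plus 1 (y axis) by group (x axis), 1 point per library, with a line at the mean of the log values. Csn2 lay between 65500 and 135000 CPM at 22 months, and at 21300 and 32100 CPM with midkine against 1220 and 667 CPM with vehicle.

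In luminal hormone-sensing cells at 22 months, some named genes rose from low levels at 3 months. Klk1 (kallikrein, a serine protease; a symbol shared by more than 1 identifier) stood at 2880 ± 1660 against 1.18 ± 2.1 CPM, a log2 change of 11.49 ± 0.97 (adjusted p = 4.13e-08). Ctxn3 stood at 210 ± 77.1 against 0.117 ± 0.138 CPM, and Spink8, a protease inhibitor of the Kazal type, at 1890 ± 136 against 40.6 ± 23.2 CPM (5.55 ± 0.68). Hpgd, which degrades prostaglandins, rose by 6.25 ± 0.56, Angptl1 by 8.65 ± 0.78 and Ppp1r1a by 5.13 ± 0.60. The amino acid transporter Slc6a14 fell from 117 ± 53.6 to 1.53 ± 1.05 CPM (-6.37 ± 1.14), the DNA repair gene Rad54b by 4.77 ± 0.87 (9.83 without replicate 3 of 22 months) and Kcnab1 by 4.12 ± 0.70. Adgrl3 had no UMI in the 4 libraries of 22 months and 5.3 ± 2.22 CPM at 3 months. Of 16 fatty acid synthesis genes 11 rose and 1 fell (12 and 1 adjusted over the list alone), with Srebf1 at 1.90 ± 0.20 (median 1.23, camera adjusted p = 4.93e-07, and adjusted p = 0.234 with an estimated correlation). The median was 0.52 among genes at 1/5 or more of their level in the highest class. Of 41 ribosomal protein genes 0 rose and 38 fell (0 and 39 adjusted over the list alone), with Rpl6 at -1.55 ± 0.13 (median -0.58, camera adjusted p = 9.16e-37, and adjusted p = 0.234 with an estimated correlation). Of 28 oxidative phosphorylation genes 17 rose and 0 fell (21 and 0 adjusted over the list alone; median 0.38, camera adjusted p = 1.43e-08, and adjusted p = 0.402 with an estimated correlation), a call that ended with no low-count filter (adjusted p = 0.147). The identity list of 16 luminal genes split, with 4 up and 4 down (4 and 4 adjusted over the list alone; median -0.02, camera adjusted p = 0.993). Of hormone response genes Fkbp5 rose by 5.26 ± 0.44 and Wnt4, a progesterone target, by 2.00 ± 0.22, while Ccnd1 fell by 1.30 ± 0.26. That list of 14 had 3 rising and 1 falling member (3 and 3 adjusted over the list alone) and was not called (camera adjusted p = 0.234). Of the 12 named genes 10 kept their call without any 1 library. Gp2 (-6.61 ± 2.2) lost it without replicate 2 of 3 months or any library of 22 months (-4.84 to -10.16), and Mcm8 (-4.42 ± 1.25) without replicate 4 of 22 months (-3.89).

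In basal cells, the contractile outer layer of the epithelium, MHC class I genes rose at 22 months, as did some genes of basal identity and some markers of other epithelium. Acta1, skeletal muscle actin, rose from 143 ± 45.9 to 1240 ± 831 CPM (3.11 ± 0.44, adjusted p = 6.73e-05), Gsta1 by 2.61 ± 0.33, Otos by 2.45 ± 0.20 and Dpysl3 by 1.94 ± 0.15. Of 17 basal identity genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), with the smooth muscle gene Tagln at 0.78 ± 0.14 and Tp63, a basal transcription factor, at -0.69 ± 0.16 (median 0.31, camera adjusted p = 0.000919, and adjusted p = 0.318 with an estimated correlation). Of 16 MHC class I genes 12 rose and 0 fell (15 and 0 adjusted over the list alone), with RT1-A1 at 1.41 ± 0.12 (median 0.74, camera adjusted p = 2.49e-12, and adjusted p = 0.234 with an estimated correlation). Of 11 other epithelial markers 5 rose and 0 fell (5 and 0 adjusted over the list alone), among them the luminal keratins Krt18 (2.74 ± 0.31) and Krt19 (1.93 ± 0.31), at a median of 0.40 (camera adjusted p = 0.000652, and adjusted p = 0.318 with an estimated correlation). That median ran from 0.22 without replicate 3 of 3 months to 0.73 without replicate 4 of 3 months, and was 0.26 without replicate 1 of 22 months. Lgr6, a receptor of epithelial stem cells, fell from 88 ± 12.2 to 34.5 ± 12.4 CPM (-1.41 ± 0.22). The cystine transporter Slc7a11 fell from 43.7 ± 5.22 to 11.9 ± 4.42 CPM (-1.89 ± 0.30) and Chac1 by 2.00 ± 0.37. Ereg, encoding epiregulin, had no UMI in the 4 libraries of 22 months against 1.09 ± 0.811 CPM, and its call ended without replicate 1 of 3 months (adjusted p = 0.0922). The other 11 named genes kept theirs without any 1 library.

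In fibroblasts at 22 months, Thy1, a surface marker of these cells, rose from 104 ± 32.1 to 498 ± 103 CPM (2.25 ± 0.33, adjusted p = 0.000158). Mgp, a matrix protein that inhibits calcification, rose from 1930 ± 454 to 7200 ± 1420 CPM (1.90 ± 0.26), and S100a4 by 1.71 ± 0.21. Eln, elastin, fell from 378 ± 74.4 to 117 ± 28.3 CPM (-1.70 ± 0.23, adjusted p = 8.38e-05), and the decoy interleukin-1 receptor Il1r2 fell from 318 ± 64.1 to 92.8 ± 25 CPM (-1.76 ± 0.31). Of 27 collagen and matrix genes 5 rose and 3 fell (7 and 4 adjusted over the list alone), without a call (median 0.11, camera adjusted p = 0.762). Of 17 MHC class I genes 14 rose and 1 fell (16 and 1 adjusted over the list alone), with Psmb9 at 1.48 ± 0.20 (median 0.80, camera adjusted p = 1.01e-12, and adjusted p = 0.234 with an estimated correlation). Of 29 interferon response genes 12 rose and 0 fell (16 and 0 adjusted over the list alone), with Isg15 at 1.49 ± 0.28 (median 0.58, camera adjusted p = 3.73e-07, and adjusted p = 0.318 with an estimated correlation). Of 20 genes linked to senescence and its secreted factors 8 rose and 1 fell (9 and 1 adjusted over the list alone), with the chemokine Cxcl1 at 1.30 ± 0.24 (median 0.68, camera adjusted p = 0.00039, and adjusted p = 0.318 with an estimated correlation). That median was 0.44 without replicate 2 of 3 months. Of 12 complement and acute phase genes 6 rose and 0 fell (6 and 0 adjusted over the list alone), with C2 at 0.83 ± 0.15 (median 0.54, camera adjusted p = 0.00122, and adjusted p = 0.402 with an estimated correlation). Markers of other cells moved as well in this class, as 4 of 9 T-cell markers rose (8 adjusted over the list alone; median 1.22, camera adjusted p = 0.000197, and adjusted p = 0.396 with an estimated correlation) and 1 of 7 endothelial markers rose (3 adjusted over the list alone; median 1.63, camera adjusted p = 0.013, and adjusted p = 0.453 with an estimated correlation). Of 7 MHC class II genes 0 rose and 3 fell (1 and 5 adjusted over the list alone; median -1.11 and, at the coarser clustering, -1.69; camera adjusted p = 0.00456, and adjusted p = 0.491 with an estimated correlation). Of the 12 named genes only Cst6 (2.87 ± 0.82) lost its call, without replicate 1, 2 or 3 of 3 months or replicate 1 of 22 months (2.05 to 3.04).

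In endothelial cells at 22 months, interferon and MHC class I genes rose and immediate early genes fell. Of 28 interferon response genes 15 rose and 0 fell (17 and 0 adjusted over the list alone), with Rtp4 at 1.14 ± 0.16 (median 0.56, camera adjusted p = 2.44e-11, and adjusted p = 0.318 with an estimated correlation). Of 17 MHC class I genes 12 rose and 0 fell (14 and 0 adjusted over the list alone), with RT1-A1 at 1.35 ± 0.09 (median 0.48, camera adjusted p = 1.22e-12, and adjusted p = 0.234 with an estimated correlation). Of 19 immediate early genes 0 rose and 11 fell (0 and 11 adjusted over the list alone), including Egr1 (-1.34 ± 0.21), at a median of -0.55 (camera adjusted p = 1.51e-07, and adjusted p = 0.318 with an estimated correlation). Of 6 MHC class II genes 0 rose and 1 fell (0 and 4 adjusted over the list alone; median -1.31, camera adjusted p = 0.00219, and adjusted p = 0.455 with an estimated correlation). Macrophage markers fell in 3 of 10 (5 adjusted over the list alone; median -1.25, camera adjusted p = 0.0356, and adjusted p = 0.545 with an estimated correlation), a call that ended at the coarser clustering (-0.37), with only the ageing libraries, and without replicate 1 or 2 of 3 months or 1, 2 or 3 of 22 months (-0.87 to -1.51). Olr1, a receptor for oxidised lipoproteins, rose from 1.78 ± 1.29 to 30.4 ± 13.8 CPM (3.94 ± 0.76, adjusted p = 0.00139), and Ifi27l2b from 326 ± 60.8 to 1180 ± 266 CPM (1.86 ± 0.19). Esm1, a marker of endothelial tip cells, fell from 115 ± 35.8 to 24 ± 12.3 CPM (-2.24 ± 0.37), Edn1, endothelin, by 1.67 ± 0.38 and the glycerol channel Aqp7 by 1.58 ± 0.21. Of the 12 named genes 10 kept their call without any 1 library. Hba-a1, a haemoglobin transcript (-4.45 ± 1.31), lost it without replicate 1 of 3 months (-2.12) or any library of 22 months, and Csf2 (-2.48 ± 0.73) without replicate 3 of 3 months (-1.98) or replicate 1, 3 or 4 of 22 months (-2.15 to -2.40).

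In macrophages at 22 months, genes of lipid-associated macrophages rose. A cluster led by Spp1 and with Trem2 among its leading genes held 6.2% of macrophages at 3 months and 22.9% at 22 months. Trem2, a lipid receptor of these cells, rose from 51 ± 13.6 to 505 ± 138 CPM (3.28 ± 0.40, adjusted p = 2.54e-05), Spp1, osteopontin, from 4.4 ± 4.94 to 1900 ± 1140 CPM (9.25 ± 1.27) and Fabp5 from 226 ± 92.7 to 1180 ± 496 CPM (2.39 ± 0.36). Of 15 genes of that list 12 rose and 0 fell (14 and 0 adjusted over the list alone), with Gpnmb at 1.94 ± 0.24 (median 1.57, camera adjusted p = 4.7e-12, and adjusted p = 0.216 with an estimated correlation). Of 18 hypoxia and glycolysis genes 11 rose and 0 fell (12 and 0 adjusted over the list alone), with Eno1 at 1.43 ± 0.17 and Ldha at 1.00 ± 0.13 (median 0.66, camera adjusted p = 6.97e-06, and adjusted p = 0.282 with an estimated correlation). Of 12 resident macrophage genes 0 passed in edgeR over all genes tested and 0 adjusted over the list alone, and the list was not called (median -0.48, camera adjusted p = 0.13). Of 31 proliferation genes 19 rose and 0 fell (21 and 1 adjusted over the list alone; median 1.93, camera adjusted p = 5.17e-07, and adjusted p = 0.396 with an estimated correlation). That median was 0.96 without replicate 2 of 22 months, and 0.46 (adjusted p = 0.0855) among genes at 1/5 or more of their level in the highest class. The co-stimulatory ligand Cd86 fell from 165 ± 55.9 to 47.3 ± 2.12 CPM (-1.79 ± 0.24), Clec4m by 4.13 ± 1.07, Retnlg by 3.57 ± 0.78 and Tmem119 by 1.99 ± 0.42. Of the 12 named genes only Hba-a1 (6.88 ± 2.25) lost its call, without any 1 library of 3 months (6.69 to 7.23) or replicate 4 of 22 months (3.43). Cxcl11 (5.54 ± 1.36) lost its own with doublets kept (2.95, adjusted p = 0.0697).

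In T cells at 22 months, naive T-cell genes fell and genes of cytotoxic and exhausted T cells, NF-kB targets and senescence rose. The class differed in its clusters, as one cluster held 76.6% of T cells at 3 months and 11.2% at 22 months. Of 15 naive T-cell genes 1 rose and 11 fell (1 and 11 adjusted over the list alone), with the homing receptor Ccr9 at -6.44 ± 0.50 (median -1.30, camera adjusted p = 6.97e-05, and adjusted p = 0.396 with an estimated correlation). Of 19 genes of cytotoxic and exhausted T cells 13 rose and 4 fell (13 and 4 adjusted over the list alone), with Nkg7 at 1.88 ± 0.16 and granzyme K, Gzmk, at 2.63 ± 0.29 (median 1.69, camera adjusted p = 0.00121, and adjusted p = 0.396 with an estimated correlation). Of 21 NF-kB chemokines and cytokines 13 rose and 1 fell (14 and 1 adjusted over the list alone), with Ccl5 at 3.40 ± 0.45 (median 1.01, camera adjusted p = 0.000138, and adjusted p = 0.337 with an estimated correlation). Both calls ended among genes at 1/5 or more of their level in the highest class, with medians of 0.67 (adjusted p = 0.122) and 0.45 (adjusted p = 0.0855). Of 19 senescence genes 13 rose and 0 fell (14 and 0 adjusted over the list alone), with the cell cycle inhibitors Cdkn2a at 3.55 ± 0.35 and Cdkn1a at 2.22 ± 0.22 (median 1.56, camera adjusted p = 0.000135, and adjusted p = 0.396 with an estimated correlation). Of 19 immediate early genes 13 rose and 0 fell (13 and 1 adjusted over the list alone; median 0.63, camera adjusted p = 0.000148, and adjusted p = 0.402 with an estimated correlation). The chemokine receptor Cxcr3 rose (49.3 ± 6.08 to 300 ± 53.9 CPM, 2.61 ± 0.22), as did the cytokine signal inhibitor Cish (2.98 ± 0.19). Myb fell from 121 ± 16.8 to 14.2 ± 6.77 CPM (-3.02 ± 0.28). Chad (4.17 ± 0.67) stood at 2.68 without replicate 3 of 22 months. Macrophage markers rose too in this class, with 7 of 12 up and 1 down (7 and 1 adjusted over the list alone; median 1.03, camera adjusted p = 0.00836, and adjusted p = 0.497 with an estimated correlation; 1.83 without replicate 2 of 3 months). Fibroblast markers did in 4 of 9 (4 adjusted over the list alone; median 1.16, camera adjusted p = 0.0356, and adjusted p = 0.561 with an estimated correlation), a call that ended without replicate 3 or 4 of 3 months or replicate 1 of 22 months (1.06, 0.84 and 1.03). All 12 named genes kept their call without any 1 library.

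The comparisons of 12 and 6 with 3 months, made in the epithelial classes, asked which changes appear at middle ages. Interferon response genes rose in secretory cells at both. Of 29 interferon genes 19 rose and 0 fell at 12 months (20 and 0 adjusted over the list alone), with Irf7, a regulator of type I interferon, going from 20.4 ± 2.98 to 64.9 ± 10.7 CPM (1.67 ± 0.19, adjusted p = 2.99e-05). The median was 1.07 (camera adjusted p = 7.22e-10, and adjusted p = 0.524 with an estimated correlation), and 0.66 among genes at 1/5 or more of their level in the highest class. At 6 months 11 rose and 0 fell (14 and 0 adjusted over the list alone), with Mx2 at 2.71 ± 0.47 (median 0.55, camera adjusted p = 4.08e-06, and adjusted p = 0.848 with an estimated correlation). Of 17 MHC class I genes 12 rose in secretory cells at 12 months and 7 at 6 months (13 and 7 adjusted over the list alone; medians 0.52 and 0.32; camera adjusted p = 6.42e-08 and 0.00097, and adjusted p = 0.705 and 0.848 with an estimated correlation). Of 43 ribosomal protein genes 14 fell at 12 months and 19 at 6 months (18 and 26 adjusted over the list alone; medians -0.26 and -0.28; camera adjusted p = 1.8e-08 and 9.27e-12, and adjusted p = 0.838 and 0.848 with an estimated correlation). Tnfsf18 (-2.46 ± 0.40), Kng1 (-2.39 ± 0.44) and Apln (2.07 ± 0.39) changed at 12 months, and Wfdc3 (1.97 ± 0.41) and Tnfsf18 (-1.84 ± 0.35) at 6 months. In all, secretory cells had 1236 genes higher and 1435 lower at 12 months and 863 and 988 at 6 months, totals of 2671 and 1851 that fell to 1648 without replicate 3 of 3 months and 773 without replicate 3 of 6 months.

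Hormone-sensing cells had 371 genes higher and 422 lower at 12 months, and 203 and 278 at 6 months. Cholesterol synthesis genes fell in them, 8 of 24 at 6 months (19 adjusted over the list alone), including Hmgcs1 (-1.60 ± 0.42). The median was -0.78 at 6 months (camera adjusted p = 6.41e-11, and adjusted p = 0.848 with an estimated correlation). At 12 months 0 rose and 3 fell (1 and 9 adjusted over the list alone) with a median of -0.48 (camera adjusted p = 1.46e-06, and adjusted p = 0.838 with an estimated correlation). The clock output gene Dbp rose at 12 months (70.7 ± 8.95 to 247 ± 63.3 CPM, 1.80 ± 0.34), and at 6 months (1.53 ± 0.34), where the call ended without replicate 3 of 6 months (1.40). The labels give no time of day. The hormone-sensing counts varied without 1 library, from 308 to 748 around 793 at 12 months, and from 103 to 591 around 481 at 6 months. Basal cells changed in 38 genes at 12 months (23 higher, 15 lower) and 183 at 6 months (82 and 101), and other divisions of the same 8 libraries gave up to 176 and 381 genes. Without 1 library, their counts ran from 11 to 89 at 12 months and from 55 to 296 at 6 months. Art3 (1.86 ± 0.30) and Ccn1 (-1.09 ± 0.17) at 12 months, and Dbp (1.66 ± 0.25) and Plekhs1 (-1.76 ± 0.33) at 6 months, kept their basal calls without any 1 library.

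The comparison of midkine with vehicle asked what added midkine does in young glands. In basal cells of midkine-treated rats, cell cycle genes rose. Ccna2, cyclin A, rose from 7.6 ± 2.91 to 69 ± 1.58 CPM (SD, n = 2 each; log2 change 3.21 ± 0.54, adjusted p = 0.00154), Cenpf, a kinetochore protein, from 1.94 ± 0.198 to 57.5 ± 1.74 CPM (4.85 ± 1.05), and Mki67 from 6.71 ± 2.89 to 103 ± 7.48 CPM (3.96 ± 0.99). Of 30 proliferation genes 21 rose and 1 fell (23 and 2 adjusted over the list alone; median 3.17, camera adjusted p = 9.37e-10, and adjusted p = 0.549 with an estimated correlation). Of 28 oxidative phosphorylation genes 11 rose and 0 fell (19 and 0 adjusted over the list alone; median 0.60, camera adjusted p = 1.33e-09, and adjusted p = 0.607 with an estimated correlation). Of 18 ATF4 and mTORC1 targets 6 rose and 0 fell (10 and 0 adjusted over the list alone), with the serine synthesis gene Psph at 1.35 ± 0.22 (median 0.55 and, without replicate 1 of vehicle, 0.32; camera adjusted p = 4.02e-05, and adjusted p = 0.543 with an estimated correlation). Of 23 cholesterol genes 0 rose and 6 fell (1 and 10 adjusted over the list alone), with Idi1 at -1.37 ± 0.27 (median -0.42, camera adjusted p = 0.011, and adjusted p = 0.674 with an estimated correlation), a call that ended without replicate 2 of vehicle (-0.04). Itga8, an integrin of contractile cells, fell from 51.5 ± 5.91 to 11.3 ± 0.504 CPM (-2.19 ± 0.23), Pcp4 from 536 ± 7.45 to 137 ± 25.7 CPM (-1.97 ± 0.24) and Acta1 by 2.01 ± 0.65 (adjusted p = 0.0484). In all 649 genes rose and 466 fell. The total of 1115 was 2116 with only the experiment's libraries and 662 with a replicate block. In simulated data of this comparison 15.8% of calls were false. Of the 12 named genes Itga8 and Pcp4 kept their call in all 4 fits without 1 library, in which the lone library of a group is assumed to vary like the others. Cenpf (4.94), Ccna2 (2.80) and Cdk1 (4.55 ± 0.93; 4.21) lost theirs without replicate 1 of vehicle, and Mki67 (3.51 to 4.44), Acta1 (-1.77 to -2.27), Cdkn3 and Pttg1 without any 1 library and with DESeq2. Basal cells carried 5542 ± 555 UMIs with vehicle and 8701 ± 1540 with midkine.

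In secretory cells of midkine-treated rats, milk genes rose. Fabp3 rose from 49.9 ± 38.5 to 2090 ± 927 CPM (5.38 ± 0.87, adjusted p = 0.000791), Wap from 51.3 ± 29.3 to 2280 ± 457 CPM (5.47 ± 1.46, adjusted p = 0.0139), Csn2 from 900 ± 410 to 24700 ± 6660 CPM (4.78 ± 1.57, adjusted p = 0.0388) and Glycam1 from 155 ± 75 to 2340 ± 261 CPM (3.91 ± 1.22, adjusted p = 0.0304). Of 19 milk and lactation genes 12 rose and 0 fell (14 and 0 adjusted over the list alone; median 1.26 and, at the coarser clustering, 0.70; camera adjusted p = 7.37e-08, and adjusted p = 0.543 with an estimated correlation). Of 28 oxidative phosphorylation genes 22 rose and 0 fell (25 and 0 adjusted over the list alone), with Ndufa2 at 1.71 ± 0.23 (median 1.04, camera adjusted p = 4.28e-17, and adjusted p = 0.543 with an estimated correlation). Of 19 immediate early genes 0 rose and 13 fell (0 and 13 adjusted over the list alone), with Egr1 going from 3580 ± 43.6 to 984 ± 78.6 CPM (-1.86 ± 0.41; list median -1.16, camera adjusted p = 5.57e-07, and adjusted p = 0.549 with an estimated correlation). This list and oxidative phosphorylation were also called in hormone-sensing, basal and endothelial cells and fibroblasts. In all 1154 genes rose and 956 fell, a total of 2110 that was lower in every fit without 1 library. Fabp3 alone of the 12 named genes kept its call in all 4 fits without 1 library. Csn2 (4.36 to 5.36) and Glycam1 (3.47 to 4.54) lost theirs without any 1 library, Wap without replicate 1 (5.01) or 2 (6.20) of vehicle or replicate 2 of midkine (5.25), Egr1 without replicate 2 of midkine (-1.79), and Kng1 (-4.10 ± 0.76) without replicate 1 of vehicle (-1.98).

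In hormone-sensing cells of midkine-treated rats, some named genes fell and others rose. The calcium-regulating hormone Stc2 fell from 90.6 ± 17.1 to 12.5 ± 3.05 CPM (-2.78 ± 0.27, adjusted p = 3.11e-06), the endocytic receptor Lrp2 from 40.4 ± 3.63 to 3.4 ± 0.17 CPM (-3.53 ± 0.49), Tsku by 2.70 ± 0.34, and the alarmin Il33 from 693 ± 199 to 106 ± 0.567 CPM (-2.70 ± 0.51). Bik, which promotes cell death, rose by 2.44 ± 0.38, and Ppp1r1a from 6.72 ± 7.8 to 126 ± 46.1 CPM (4.48 ± 0.94). Ctxn3 had no UMI in the 2 vehicle libraries and 2.22 ± 0.839 CPM with midkine. Of 17 FOXO targets 1 rose and 5 fell (1 and 8 adjusted over the list alone), with Gadd45a at -2.26 ± 0.38 (median -0.56, camera adjusted p = 0.00102, and adjusted p = 0.543 with an estimated correlation), a call that ended among genes at 1/5 or more of their level in the highest class (-0.23, adjusted p = 0.195). Of 14 proliferation genes 2 rose (9 adjusted over the list alone; median 0.87, camera adjusted p = 2.77e-05, and adjusted p = 0.543 with an estimated correlation), with a median of 0.57 without replicate 1 of midkine. In all 211 genes rose and 381 fell, a total of 592 that stood at 1981 at the coarser clustering. Of the 12 named genes Bik, Lrp2, Stc2 and Tsku kept their call without any 1 library. Ctxn3 lost its own in each such fit, Il33 without replicate 2 of midkine (-2.70), and Ppp1r1a without replicate 1 of vehicle (3.32) or replicate 2 of midkine (4.07).

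Outside the epithelium fewer genes passed with midkine. In edgeR 0 genes passed in endothelial cells, with 727 at an unadjusted p under 0.05 14 by DESeq2 and 220 with no low-count filter, and 0 in macrophages, with 698 and 4. T cells had 5 genes higher and 8 lower, including S100a4 (63.1 ± 6.84 to 588 ± 541 CPM with midkine, 3.05 ± 0.55), Pde7a (1.53 ± 0.24) and Irf1 (-1.12 ± 0.22). The total of 13 was 127 by DESeq2 and 161 with no low-count filter. Fibroblasts had 1 gene higher, Anapc13 (1.65 ± 0.24), and 4 lower, including the B-cell chemokine Cxcl13 (790 ± 825 to 5.63 ± 7.96 CPM, -6.61 ± 1.05). Their total of 5 was 106 by DESeq2 and 23 with no low-count filter. None of the T-cell and fibroblast genes named here kept its call in every fit without 1 library, where S100a4 stood at 1.68 without replicate 1 of midkine and Cxcl13 at -15.16 without replicate 2 of midkine. With an unnamed cluster added to the fibroblasts, Anapc13 lost its call (0.64, adjusted p = 0.0571) and Cxcl13 stood at -3.77. In simulated data of this size, 37.9% of 4-fold changes were recovered in fibroblasts, 59.1% in T cells, 71.2% in macrophages and 77.3% in endothelial cells. Of 15 naive T-cell genes 1 fell in T cells (3 adjusted over the list alone; median -0.60, camera adjusted p = 1.78e-05, and adjusted p = 0.543 with an estimated correlation). Their median ran from -0.36 without replicate 1 of midkine to -1.41 without replicate 2 of midkine.

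**Figure D4:**
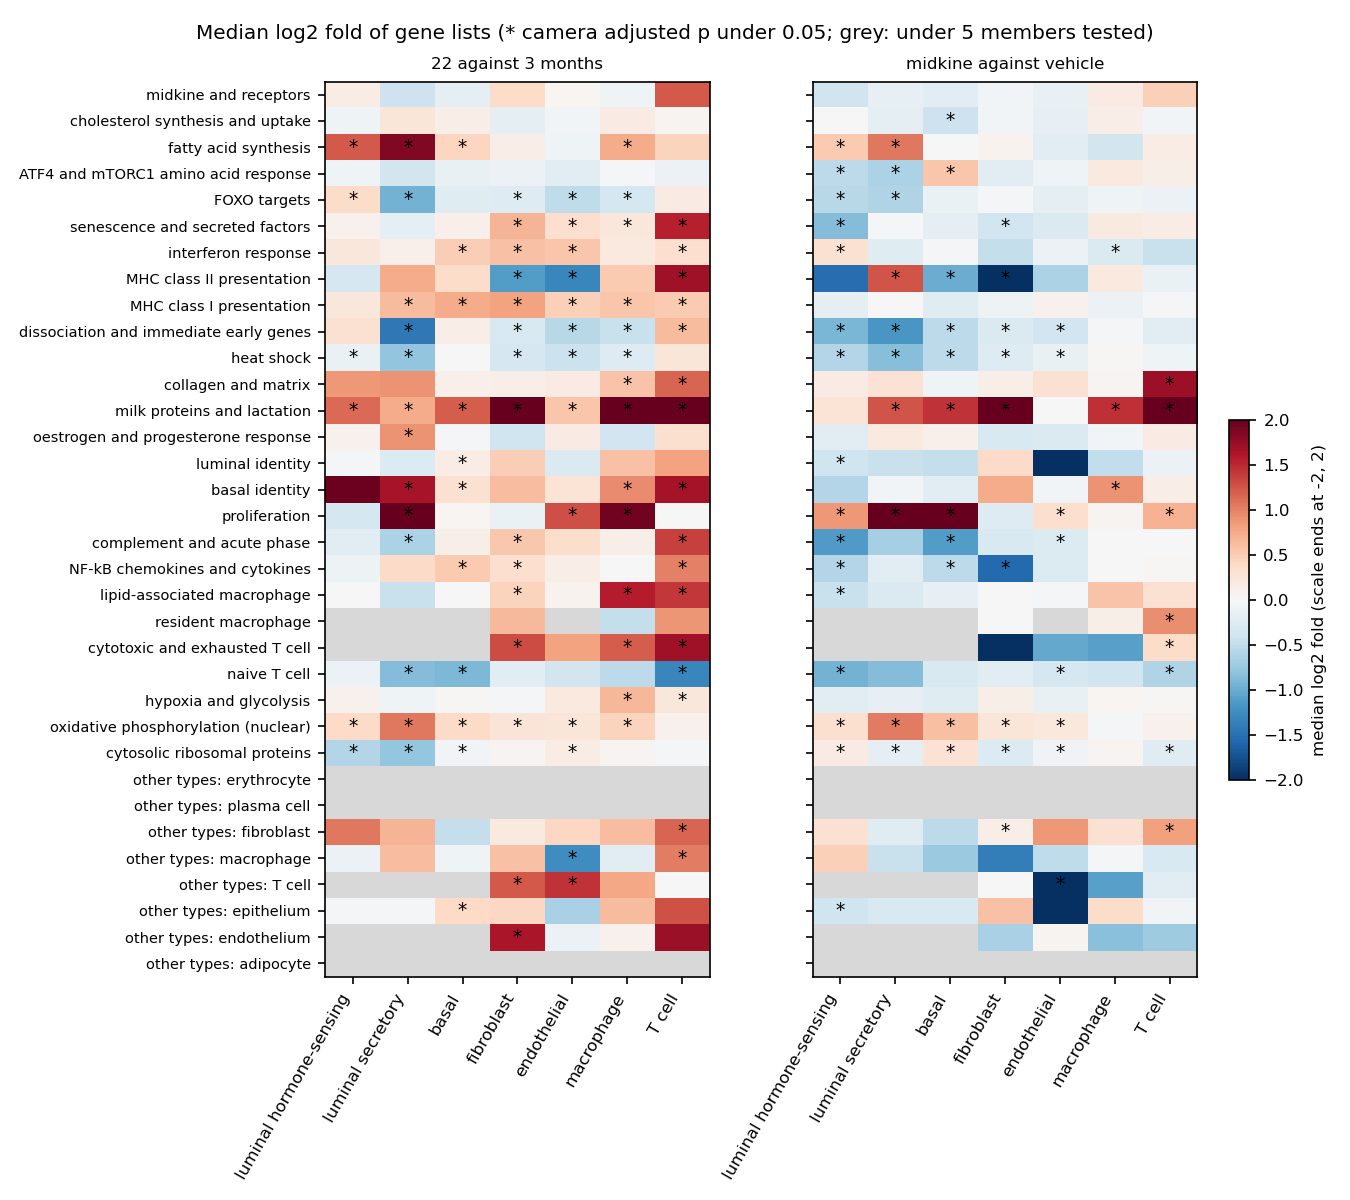
Median log2 change (colour) of each gene list (y axis) in each class (x axis), for 22 against 3 months and midkine against vehicle. A star marks a camera call, and grey marks lists with under 5 members tested. In luminal secretory cells oxidative phosphorylation stands at 1.05 and 1.04.

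Genes that changed between 22 and 3 months were then followed under midkine, to ask whether the treatment moves them the same way. In secretory cells 4881 of 6286 such genes (77.6%) had the same sign with midkine, with a mean signed log2 change of 0.511 (fry adjusted p = 0.00464 over 7 classes). Of those called in both comparisons, 1455 went the same way and 93 the opposite way. In hormone-sensing cells 1366 of 2145 (63.7%) had the same sign, with a mean of 0.252 (adjusted p = 0.0327), and 169 genes called in both went the same way against 50. Basal cells gave 0.040 (54.4% with the same sign, adjusted p = 0.629), with 91 genes against 78. Fibroblasts (0.184, adjusted p = 0.248), T cells (0.248, adjusted p = 0.151), endothelial cells (0.072, adjusted p = 0.482) and macrophages (0.104, adjusted p = 0.693) did not pass either. The rats of the midkine experiment were 2 months old and untreated 3-month-old rats were not its controls, so no library is shared by the comparisons. With only the 4 libraries of the midkine experiment in its model, neither call passed, at 0.473 (adjusted p = 0.162) in secretory and 0.225 (adjusted p = 0.171) in hormone-sensing cells. In camera with an estimated correlation, genes higher and lower with age gave adjusted p = 0.0449 and 0.0756 in secretory and 0.203 and 0.264 in hormone-sensing cells. The call ended in secretory cells without replicate 1 of vehicle, and in hormone-sensing cells without replicate 1 of vehicle, replicate 2 of midkine (0.204), replicate 2 of 3 months, or replicate 1 or 3 of 22 months. These genes were chosen on the ageing libraries, so their direction there is not independent evidence.

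Mdk itself (ENSRNOG00000017560) was highest in basal cells. There it stood at 2680 ± 374 CPM at 22 months and 1420 ± 404 CPM at 3 months, with no overlap of libraries (0.91 ± 0.20, adjusted p = 0.00349). It was not called in basal cells at 12 months (0.25, adjusted p = 0.65) or 6 months (0.14, adjusted p = 0.802). With midkine treatment it stood at 1390 ± 106 against 919 ± 136 CPM (0.59 ± 0.28, adjusted p = 0.176), and passed with no low-count filter (adjusted p = 0.0201) and with only the experiment's libraries (adjusted p = 0.0159). Fibroblasts held 422 ± 61.8 CPM at 22 months and 320 ± 50.5 at 3 months (0.40 ± 0.21, adjusted p = 0.236). In secretory cells it was called higher at 22 months (9.76 ± 3.49 to 30 ± 11.7 CPM, 1.61 ± 0.26), with midkine (2.05 ± 0.49) and at 12 months (0.82 ± 0.28, adjusted p = 0.0402), but not at 6 months (0.67 ± 0.27, adjusted p = 0.093). The call at 12 months ended at the coarser clustering (0.81, adjusted p = 0.0616) and without replicate 1, 2 or 3 of 3 months or replicate 2 or 4 of 12 months (0.69 to 0.78). In T cells it was called higher at 22 months at low levels (1.14 ± 0.253 to 2.82 ± 0.718 CPM, 1.28 ± 0.34, adjusted p = 0.0047). Macrophages gave 0.84 ± 0.38 at 22 months (adjusted p = 0.13), and endothelial cells 0.91 ± 0.65 (adjusted p = 0.4). With midkine, fibroblasts gave 0.15 ± 0.34, endothelial cells 1.03 ± 0.78, macrophages 0.30 ± 0.71 and T cells 1.45 ± 0.97, at adjusted p of 0.599 or more. In hormone-sensing cells it was called higher with midkine (4.24 ± 2.84 to 48.8 ± 25.7 CPM, 3.32 ± 0.83), but not at 22 months (1.21 ± 0.77), 12 months (0.99 ± 0.58) or 6 months (-0.59 ± 0.69), where the first 2 passed without replicate 4 of 3 months (2.33 and 2.11) or with no low-count filter, and the third turned to 0.53 without that library. The calls with midkine in secretory and in hormone-sensing cells each ended in some of the fits without 1 library, where Mdk stayed higher. Secretory, hormone-sensing and T-cell levels were 0.0101, 0.00972 and 0.000873 of the basal level. The list of midkine and its receptors was called in no class and comparison, and came nearest in T cells at 22 months, where 7 of 11 members rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0509). Lists of erythrocyte, plasma cell and adipocyte markers never had 5 members tested.

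**Figure D5:**
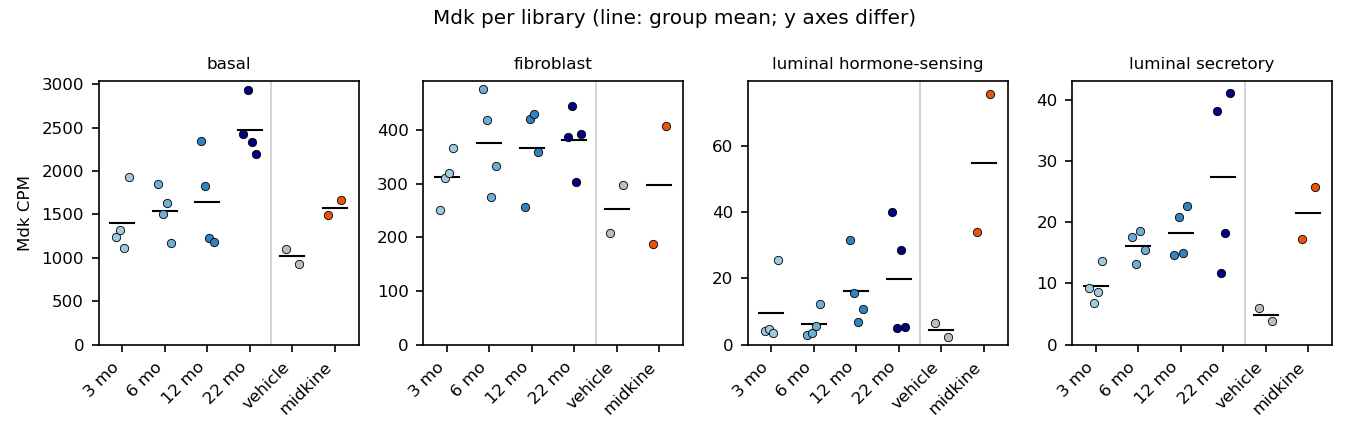
Mdk in plain CPM (y axes, which differ in scale) by group in 4 classes, 1 point per library, with a line at each group mean. Basal libraries lie between 1110 and 1930 CPM at 3 months and between 2190 and 2930 CPM at 22 months.

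With 2 libraries per treatment the smallest exact permutation p is 0.333, so shares of cells under midkine are given per library with Wilson 95% intervals, which cover counting error only. B cells made up 33% (32 to 34.1) and 21.8% (20.7 to 22.9) of named cells in the vehicle libraries. In the midkine libraries they made up 0.0328% (0.009 to 0.12), which was 2 of 6093 cells, and 15.8% (14.8 to 16.9). T cells made up 20% (19.1 to 20.9) and 15.1% (14.2 to 16.1) with vehicle, and 1.12% (0.881 to 1.41) and 9.26% (8.45 to 10.1) with midkine. Plasma cells were 0 of 6093 in replicate 1 of midkine, which allows a share of up to 0.0492%. Basal cells made up 13.9% (13.1 to 14.7) and 11.8% (11 to 12.7) with vehicle, and 27.7% (26.5 to 28.8) and 21.5% (20.4 to 22.8) with midkine. Secretory cells made up 7.25% (6.68 to 7.86) and 8.41% (7.71 to 9.16) with vehicle, and 24.6% (23.6 to 25.7) and 9.53% (8.7 to 10.4) with midkine. Hormone-sensing cells made up 8.09% (7.49 to 8.73) and 5.09% (4.55 to 5.7) with vehicle, and 11.6% (10.8 to 12.4) and 6.11% (5.44 to 6.85) with midkine.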

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

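Of the tests here, only that of sequencing depth on the proliferation list was set before its result was seen, and the tests of free RNA, single libraries, cycling markers, lymph-node tissue and other divisions of the libraries were chosen after it.

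Milk protein genes in luminal secretory cells at 22 months are the first pattern, with Csn2 at 65500 to 135000 CPM in the 4 libraries. Free RNA released by other cells may add such transcripts, but secretory cells held, as a median over these genes, 731 to 1640 times the UMIs per cell of T cells of the same library, and after subtraction of the latter the 12 genes called higher stayed at a median log2 change of at least 1.98 in each library of 22 months (10 of the 12 above 3 months in replicate 1, 12 in the others), which argues against it as the whole cause. A single library was argued against too, since the list stayed called without any 1 library, at a lowest median of 0.41 (without replicate 2 of 22 months, against 0.74). What stays open is the reproductive state and hormone level of the animals, which the labels do not give, and age itself, neither of which was tested apart.

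Proliferation genes in basal cells with midkine are the second pattern. Their list was also called in hormone-sensing, secretory, endothelial and T cells. The unnamed cluster of cycling luminal cells, left out of these classes, held 7 cells with vehicle and 51 with midkine. Greater depth per cell with midkine might raise such counts: after each cell was thinned to 2000 UMIs, basal cells with at least 2 UMIs of the list made up 41.5% and 41.6% with midkine against 30.6% and 26.4% with vehicle, a ratio of 1.36 that leaves depth open for the list as a whole. Cells with at least 2 UMIs of the cycling markers argue against depth for these, at 10.2% (Wilson 95% interval 8.81 to 11.7) and 12.4% (10.5 to 14.7) with midkine against 0.299% (0.102 to 0.874) and 0.312% (0.0857 to 1.13) with vehicle, a ratio of 32.7 for the nearest libraries, and endothelial cells, thinned alike, stood at 0.966% and 1.78% with midkine against 0% (0 of 359) and 0.399% with vehicle. The list stayed called without any 1 library, at a lowest median of 2.62, which argues against a single library for the list, although without replicate 1 of vehicle 1 gene was called higher, against 11 or 12 without each other library and 21 with all. An effect of midkine, or a difference between the 2 rats or pools of each group such as cycle stage, was not told apart by these tests, since libraries of 12 months alone ranged from 0% to 8.09% in the same measure, and free RNA was not tested.

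Shares of T and B cells at 22 months are the third pattern. Less lymph-node tissue in the older samples could lower B cells and would lower T cells with them. Relative to cells that are neither, T cells stood at 84.1 ± 23.6 against 44.8 ± 20.4 per 100 cells (log2 difference 0.98, exact p = 0.0571) and B cells at 10.1 ± 5.93 against 81.6 ± 27.6 (-3.13, exact p = 0.0286; SD, n = 4 each). Lymph-node tissue and age cannot be told apart for either share, since the T-cell libraries overlap and a midkine library of rats treated at 2 months also held few B cells, at 0.0332 per 100 such cells. That library held few T cells too (1.13, against 42.5 and 24 with vehicle), unlike those of 22 months.

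At 22 months no other of the 35 divisions of the 8 libraries called as many genes (1 of 35, the real one). Hormone-sensing cells gave 2145 against at most 160, secretory cells 6286 against 25 and basal cells 1304 against 34. Fibroblasts gave 1716 against 0, endothelial cells 1338 against 4, macrophages 1998 against 283 and T cells 4964 against 128. The real one also ranked first in hormone-sensing cells at 12 months (793 against 24) and 6 months (481 against 171). It did in secretory cells too (2671 against 154 and 1851 against 336). This proportion is the smallest possible and unadjusted, and a batch tied to age could give it too. Chance stays open in basal cells, where 3 of 35 divisions gave as many genes at 12 months (38, highest other 176). At 6 months 2 of 35 did (183, highest other 381). These counts point to a structure among the libraries other than age.

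A gap to the rest of the group singled out 6 of the 104 groups of values examined, and chance does so in about 1 in 20 groups. B cells made up 24.6% of named cells in replicate 2 of 3 months. Dendritic cells made up 1.83% in replicate 4 of 22 months. Endothelial cells made up 2.78% in replicate 4 of 3 months. Plasma cells made up 0.702% in replicate 3 of 12 months. Mdk stood at 9.35 CPM in endothelial cells of replicate 2 of 22 months. It stood at 25.5 CPM in hormone-sensing cells of replicate 4 of 3 months.

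Some lists moved in opposite directions between classes at 22 months. The 14 pairs of classes given were picked because the list was called in both, in opposite directions and with at least 3 genes called each way, in these same libraries, so their differences (in mean log2 CPM of the list) were not tested independently. The change of FOXO targets in hormone-sensing cells exceeded that in endothelial cells by 0.75, in fibroblasts by 0.72, in secretory cells by 1.41 and in macrophages by 0.81 on the log2 scale, but the hormone-sensing call ended with no low-count filter (where its direction turned), under the 1/5 rule and without replicate 1 or 4 of 3 months or 1 of 22 months (0.29, 0.22, 0.25), and the secretory one under the 1/5 rule. The change of immediate early genes in T cells exceeded that in endothelial cells by 1.13, in secretory cells by 2.26 and in macrophages by 0.95. That of ribosomal protein genes in endothelial cells exceeded that in basal cells by 0.27, in hormone-sensing cells by 0.72 and in secretory cells by 1.06. That of complement genes exceeded the change in secretory cells by 1.66 in T cells and by 1.15 in fibroblasts. That of MHC class II genes in T cells exceeded the one in fibroblasts by 2.07, and that of macrophage markers in T cells exceeded the one in endothelial cells by 1.72. With fewer genes called, MHC class II genes in T cells differed from endothelial cells by 2.61 and immediate early genes from fibroblasts by 0.9.

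Clusters that stayed unnamed took large shares of single libraries. Cluster 21 made up 26.5% of the kept cells of replicate 1 of 3 months (Wilson 95% interval 25.8 to 27.3). Cluster 22 made up 18.9% of replicate 1 of vehicle (18.1 to 19.6) and 0.0402% of replicate 2. Cluster 13 made up 23.5% of replicate 2 of midkine (22.5 to 24.6), 6.03% of its replicate 1, and 1.98% and 18.5% of the vehicle libraries.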

How the results depend on the processing

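The alternatives that kept only genes at 1/5 or more of their level in the highest class, or added cluster 13 to the fibroblasts, were chosen after the data were seen, and the others were planned.

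Kept results come first, each total leaving aside the fits without 1 library. Counts of genes stayed within 1.5 times their value in 146 of 182 comparisons with an alternative, and at 22 months in each of the 7 classes under each of them. Named genes kept direction and call in 1468 of 1524, called lists in 1482 of 1859 and Mdk in 156 of 164. Under the free-RNA rule Mdk was left only in basal cells and fibroblasts. Ageing genes under midkine kept theirs in 61 of 71, and shares in 71 of 75.

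Counts of genes moved as follows, with the reported count in brackets. DESeq2 gave 127 [38] in basal cells at 12 months and 319 [183] at 6 months. With midkine it gave 106 [5] in fibroblasts, 127 [13] in T cells, 14 [0 in edgeR, 727 at an unadjusted p under 0.05] in endothelial cells and 4 [0 in edgeR, 698 unadjusted] in macrophages. Without the low-count filter, which tests more genes, basal cells gave 274 at 12 months and 466 at 6 months, and hormone-sensing cells 911 [481] at 6 months. With midkine it gave 1151 [592] in hormone-sensing cells, 23 in fibroblasts, 220 in endothelial cells, 1 in macrophages and 161 in T cells. With only the libraries of the experiment compared, and so fewer to estimate the spread from, basal cells gave 24 at 12 months, 108 at 6 months and 2116 [1115] with midkine. Midkine counts were then 222 in hormone-sensing cells, 1 in fibroblasts, 1 in macrophages and 6 in T cells. At the coarser clustering midkine counts were 1981 in hormone-sensing cells, 3 in fibroblasts and 3 in T cells. The stricter cell filter gave 3 in fibroblasts and 21 in T cells with midkine, doublets kept gave 3 in fibroblasts, RLE normalization gave 8 in T cells, the 1/5 rule gave 7 in T cells and cluster 13 gave 107 in fibroblasts. The cause was not tested for these counts beyond the numbers of genes and libraries named.

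A replicate block, which takes equal replicate numbers as paired, gave 281 in hormone-sensing cells at 6 months, and in basal cells 23 at 12 months, 64 at 6 months and 662 with midkine. It gave 18 in endothelial cells and 7 in T cells with midkine. The numbers gave no sign of pairing: correlations between libraries of the same number ran from -0.51 to 0.35 in the ageing series and from -0.07 to 0.24 in the midkine experiment, and 12 of 112 and 16 of 28 library profiles correlated best with their own number.

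Called lists at 22 months went from 88 to 48 under the 1/5 rule. Those at 12 months went from 17 to 28 with no low-count filter and to 4 by fry, those at 6 months from 19 to 7 by fry, and those with midkine from 65 to 25 by fry. In camera with an estimated correlation 0 passed. This rests on the larger correlation allowed between genes, so the list calls depend on the preset one. The direction in camera turned for FOXO targets of hormone-sensing cells at 22 months (median 0.36 to 0.31) and oxidative phosphorylation of basal cells at 12 months (0.22 to 0.19) with no low-count filter, and neither was then called. The median turned for proliferation in secretory cells at 22 months under the 1/5 rule (3.40 to -0.07) and for fibroblast markers in fibroblasts with midkine and cluster 13 (0.14 to -0.21). The cause was not tested.

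The ageing genes followed under midkine lost their calls with only the experiment's libraries, at 0.473 in secretory and 0.225 in hormone-sensing cells. By camera, genes higher with age gave -0.021 in basal cells, -0.153 in fibroblasts, 0.086 in endothelial cells and 0.125 in T cells. Genes lower with age gave 0.120 in basal cells, 0.608 in fibroblasts and 0.375 in T cells. Each of these 7 passed except -0.021, and with an estimated correlation none did (adjusted p from 0.159 to 0.867). Camera compares with other genes, so -0.153 passed as higher than those. With cluster 13 fibroblasts passed at 0.194. The cause was not tested.

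Mdk passed with no low-count filter in hormone-sensing cells at 22 months (1.17) and 12 months (0.97), in secretory cells at 6 months (0.68) and in basal cells with midkine (0.62, and 0.62 with only the experiment's libraries). At the coarser clustering it no longer passed in secretory cells at 12 months (0.81). In endothelial cells at 22 months it went from 0.91 to -0.29 with doublets kept and -1.27 at the coarser clustering, uncalled throughout. The coarser clustering also turned 3 list members with midkine, Plin2 in hormone-sensing cells (0.86 to -2.08), Cyp51 (-0.70 to 0.06) and Foxp1 (-0.80 to 0.06) in secretory cells. Dendritic cells at 22 months went from 0.03 to -0.05 (log2 share) with doublets kept and to -0.02 percentage points on the raw scale. With the stricter cell filter the share of the epithelium passed for hormone-sensing (-1.69) and basal cells (0.71). The cause was not tested.

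Fits without 1 library assume that a library left alone in its group varies like those of the other groups. Lowest and highest values follow, with the library left out. Hormone-sensing counts ran from 308 (3 months 3) to 748 (3 months 4) at 12 months, 103 (6 months 3) to 591 (3 months 4) at 6 months and 73 (midkine 2) to 630 (vehicle 2) with midkine. Secretory counts ran from 1648 (3 months 3) to 2700 (12 months 3), 773 (6 months 3) to 1954 (3 months 4) and 611 (midkine 2) to 1089 (midkine 1). Basal counts ran from 835 (22 months 2) to 1428 (3 months 4) at 22 months, 11 (12 months 2) to 89 (3 months 4) at 12 months, 55 (3 months 3) to 296 (3 months 4) at 6 months and 81 (vehicle 1) to 635 (vehicle 2) with midkine. Fibroblast counts ran from 1085 (22 months 3) to 1523 (3 months 4) at 22 months and 0 (midkine 2) to 415 (vehicle 2) with midkine. Midkine counts ran from 0 (vehicle 1) to 158 (vehicle 2) in endothelial cells, 0 (vehicle 1) to 6 (vehicle 2) in macrophages and 0 (vehicle 1) to 234 (midkine 2) in T cells. Ageing genes under midkine ran from 0.204 (midkine 2) to 0.313 (vehicle 2) in hormone-sensing, 0.461 (midkine 2) to 0.596 (vehicle 2) in secretory and -0.026 (3 months 3) to 0.188 (3 months 4) in basal cells. Fibroblast markers in fibroblasts ran from -0.29 (vehicle 1) to 0.97 (vehicle 2) and ribosomal genes in endothelial cells from -0.18 (vehicle 2) to 0.07 (vehicle 1), both with midkine. Mdk in hormone-sensing cells ran from 0.56 (22 months 1) to 2.33 (3 months 4) at 22 months, 0.43 (12 months 1) to 2.11 (3 months 4) at 12 months, -1.12 (6 months 4) to 0.53 (3 months 4) at 6 months and 2.72 (midkine 2) to 4.34 (vehicle 1) with midkine. In secretory cells it ran from 0.69 (3 months 2) to 1.08 (3 months 4) at 12 months, 0.54 (3 months 2) to 0.93 (3 months 4) at 6 months and 1.70 (vehicle 2) to 2.48 (vehicle 1) with midkine. With midkine it ran from -0.54 (midkine 2) to 0.68 (vehicle 2) in fibroblasts, -0.35 (midkine 1) to 1.72 (vehicle 1) in endothelial cells, -0.48 (midkine 1) to 0.89 (midkine 2) in macrophages and -5.39 (midkine 2) to 1.79 (midkine 1) in T cells. Log2 shares at 22 months ran from -0.35 (22 months 3) to 0.17 (22 months 4) for secretory, -0.02 (22 months 3) to 0.73 (22 months 4) for basal and -0.12 (3 months 4) to 0.21 (3 months 3) for dendritic cells. Beyond the smaller number of libraries, the cause was not tested.

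At the depths, spread and numbers of libraries here, which were not varied apart, small changes are found in part. In simulated data 2-fold changes were recovered in 59.7% to 74.6% of genes at 22 months over the 7 classes and in 5.97% to 58.2% with midkine, and up to 15.8% of calls were false (basal cells with midkine).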

Other observations

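No test was added for this part, and the values in it were picked after they were seen.

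In endothelial cells at 22 months 13 of 22 proliferation genes rose and 1 fell (16 and 1 adjusted over the list alone; median 1.29, camera adjusted p = 3.31e-06, and adjusted p = 0.318 with an estimated correlation). The median was 0.68 with only the ageing libraries, and 0.42 among genes at 1/5 or more of their level in the highest class, where the call ended (adjusted p = 0.235).

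Replicate 4 of 3 months stood apart in several classes. Its secretory cells held 9070 CPM of Csn2, 36300 of Csn1s1 and 885 of Wap, against 176 to 1180, 7010 to 12300 and 31 to 108 in the other 3 libraries of that age. After thinning to 2000 UMIs, cells with at least 2 UMIs of the cycling markers made up 7.37% of its basal cells (Wilson 95% interval 4.59 to 11.6) and 0% to 0.998% of those of the other 3. Basal counts of genes at 12 and 6 months were higher without it.

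Other shares of named cells in the midkine experiment follow, with Wilson 95% intervals for counting error. Endothelial cells made up 5.97% (5.46 to 6.53) and 12.2% (11.3 to 13) with vehicle and 17% (16 to 17.9) and 9.89% (9.05 to 10.8) with midkine. Macrophages made up 1.85% (1.57 to 2.18) and 6.52% (5.9 to 7.2) with vehicle and 3.97% (3.51 to 4.49) and 9.6% (8.77 to 10.5) with midkine. Fibroblasts made up 0.937% (0.743 to 1.18) and 5.77% (5.19 to 6.41) with vehicle and 0.837% (0.637 to 1.1) and 4.12% (3.57 to 4.74) with midkine. These shares leave out cluster 13, in which fibroblast markers were detected and which held 1578 cells with vehicle and 1982 with midkine.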
